A study of Caenorhabditis elegans with 2 samples.

How the data were processed

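Chromatin immunoprecipitation with sequencing was done on 2 biological replicates of whole L4 larvae that express GEI-8 with a C-terminal GFP and FLAG tag, and both belong to 1 group. Chromatin was fragmented by sonication, per the labels. For each replicate, and for both pooled, the deposited files hold a relaxed list of 30000 peaks that includes background and serves as input to the irreproducible discovery rate (IDR) procedure, and 1 further list of 1053 peaks is the deposited set after the IDR threshold. Per the labels and the texts deposited beside the files, each list was called against 1 control alignment, the same for both replicates, so the lists are not fully independent of each other, and coordinates are in assembly ce11. The aligner, the peak caller and their versions are not given in the sources used here. The control reads, alignments and coverage tracks were not used here.

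The value used to rank peaks is the signal that the authors' peak caller gave each peak, and its size is comparable between lists only by rank. A linear correlation of the log2 signal between the replicates, which does not depend on the scale of either list, and a difference of log2 signal between peaks of the same list were the uses other than by rank. The deposited −log10 q-value of each peak was used only to describe the list, whose weakest peak had a q-value of 0.00724. The summit position comes from the deposited peak offset. The replicate lists have a fixed width for nearly all peaks (456 bp in replicate 1 and 450 bp in replicate 2), and 977 of the 1053 reproducible peaks are 450 bp wide, so peak widths carry little information on the width of binding. The IDR list turned out to equal the 1053 strongest peaks of the pooled list. It therefore sets a number of peaks, and a single peak on it need not be strong in both replicates. For this reason ranks in each replicate are given beside named peaks. No read counts are in the files, so depth per library is unknown and the intervals cover only the counting error of genes or peaks.

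Peaks were joined to the Ensembl annotation of assembly WBcel235, release 115, which is the assembly ce11, and to its genome sequence, and all peaks lay within its chromosome lengths. Coordinates are 1-based. A gene was called bound when a summit lay between 1000 bp upstream and 200 bp downstream of its annotated 5′ end, and the same window was used for RNA genes. Many worm transcripts are trans-spliced, so the true start of transcription can lie upstream of the annotated 5′ end. What lies at a summit was read from the annotation in the order RNA gene or pseudogene, coding exon, 5′ UTR, 3′ UTR, intron, intergenic. Categories of peaks were assigned in the order tRNA, snoRNA, protein-coding promoter. Bound genes were compared with others by Fisher's exact test, with genes as the unit and all 19973 nuclear protein-coding genes as background, and genes that share a peak are not independent. Shares were compared with 1000 rotations, in which all peaks of a chromosome are moved by the same random distance. Transgene loci were compared with 10000 random windows, and the confidence level of all intervals is 95%. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

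The groups, tests, thresholds (adjusted p of 0.05), 28 gene lists, processing alternatives and the rule for naming genes were fixed before the data were examined. The rule took the protein-coding gene nearest to each of the 15 strongest peaks, up to 3 members with the highest signal from each list past the threshold, 1 member from each of the 5 other lists with the highest share, gei-8, unc-119, and 8 enriched 6-mers with the smallest adjusted p. The gene lin-66 was named in addition after its value was seen. Of the listed genes, 1 was not found in the annotation. The lists were of nuclear hormone receptors, ribosomal proteins, cuticle collagens, histones, homeobox genes, bHLH and T-box genes, neuropeptides, insulin-like peptides, xenobiotic enzymes, heat shock proteins, proteasome, respiratory chain, chemoreceptors, F-box genes, C-type lectins and antimicrobial genes, sperm genes, hedgehog-related and patched-related genes, fatty acid metabolism, translation factors and tRNA synthetases, splicing factors, synaptic transmission, muscle structure, intestine, germline, molting and epidermis, heterochronic genes, corepressor, deacetylase and DREAM genes, and the Wnt pathway.

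The alternatives were the stronger 50% of the peaks, 2 times as many peaks from the pooled list, promoter windows of 500 bp upstream to 100 bp downstream and 2000 bp upstream to 200 bp downstream, overlap of the whole peak in place of the summit, each replicate alone, leaving out the transgene loci, a rotation test for the lists, leaving out genes within 1000 bp behind another gene on the same strand, and giving each peak to 1 gene. Other alternatives changed the overlap rule, the 6-mer windows and the flanks. Settings that left out peaks near tRNA and snoRNA genes, or kept only peaks strong in both replicates, were added after the data were seen, as were the rotation test for the RNA classes and the analyses of tRNA sequence copies and amino acid types.

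The tests were tested on simulated data. In 20 draws of random peaks among 19973 genes with peaks added at 15% of the members of 1 list, that list was called enriched in 20, and 1 call was made among lists that share no gene with it. The random peaks were spread evenly along the chromosomes, whereas peaks of the data favoured promoters. The rate of false list calls in the data is therefore not shown by these draws. Only lists of at least 60 members were planted. These draws therefore do not show how often an enrichment of the shorter heterochronic, heat shock, corepressor and respiratory chain lists would be found. A planted tRNA class was called in 20 of 20 draws. Random peaks gave a promoter share past the threshold in 0 of 20 draws, and lists that shared 60% of their peaks gave a mean overlap of 60.4%. All 5 6-mers planted in 10% of sequences were found, with 2 calls among 6-mers that share no 5 bases with them. Simulated summits and flanks had the same base composition, unlike those of the data, so the rate of false 6-mer calls in the data is not shown by this.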

Results

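GEI-8, the Caenorhabditis elegans relative of the vertebrate corepressors NCoR and SMRT, was mapped on chromatin in L4 larvae, the last larval stage before adulthood. The worms were of strain OP589, which carries an integrated transgene with GEI-8 fused to TY1, eGFP and FLAG tags together with an unc-119 rescue gene, and tagged protein was precipitated with an antibody against GFP. Whole animals of both sexes were collected at 48 hours after synchronisation as starved first-stage larvae, so each value is an average over all tissues. There was 1 group with 2 biological replicates, and no mutant, other stage or untagged strain was analysed here. The design therefore gives the sites where peaks were called, how well the replicates matched, and which genes lay at those sites. Below, a bound gene is one with a summit in its promoter window. The files hold peaks and not reads, so the sequencing depth of each library is unknown.

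The reproducible list held 1053 peaks that covered 448001 bp, or 0.447% of the nuclear genome. The strongest lay on chromosome X at 12872317 to 12872631 (all positions are in build ce11, also called WBcel235), in intergenic DNA 5005 bp upstream of bcat-1, a branched-chain amino acid aminotransferase gene, and was ranked 3 in replicate 1 and 2 in replicate 2. Its summit lay nearer to an annotated ncRNA gene, T14G8.5, at a distance of 295 bp. The next strongest peak was in an intron of pxn-1, a peroxidasin gene (V, 8500411 to 8500705), and its summit lay 29 bp from the start of a snoRNA gene inside that intron and also within 1000 bp of a tRNA gene, so it was counted below among the peaks near tRNA genes. It was ranked 1 and 7 in the replicates. A peak in an intron of pqn-41 (III, 1921243 to 1921635) was ranked 4 in both. The signal value, which is the authors' own value per peak and is comparable between lists only by rank, was 623, 614 and 611 at these sites against a median of 162 over the reproducible list.

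Among the 15 strongest peaks, 4 had a summit in the promoter of a protein-coding gene and away from tRNA and snoRNA genes. These were the promoters of rpl-3, a large ribosomal subunit gene (III, 3867381 to 3867715, summit 316 bp upstream, intergenic), of tag-340 (III, 4899799 to 4900064, 603 bp upstream, inside an annotated ncRNA gene), of epn-1, an epsin gene of endocytosis (X, 14818870 to 14819073, 432 bp upstream, intergenic), and of tasp-1, a taspase gene (III, 10759117 to 10759376, 54 bp upstream, intergenic). The epn-1 summit lay nearer to an annotated ncRNA gene, T04C10.8, at a distance of 35 bp. A pair of adjoining peaks lay in ppfr-1, a protein phosphatase subunit gene (I, 9382848 to 9383290), each with its summit within 20 bp of the start of one of a pair of ncRNA genes annotated on opposite strands. The peak nearest to F55C5.17 (V, 12303492 to 12303784) had its summit 37 bp from the start of a snoRNA gene. The other strong sites were intergenic near sup-26 (III, 4281970 to 4282323, 1984 bp upstream) and T04C4.3 (IV, 2219359 to 2219808, 2728 bp upstream), or in introns, 3368 bp inside Y111B2A.12 (III, 12612541 to 12612776) and 6886 bp inside pkg-2 (IV, 8527612 to 8527957). A further strong peak in an intron of pqn-41 (III, 1925058 to 1925532) had the start of F53A3.1 as its nearest 5′ end, 18288 bp away, but lay beyond the 3′ end of that gene and not inside it.

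The replicates shared most of their strongest sites. Of the 1053 strongest peaks of replicate 1, 651 overlapped one of the 1053 strongest of replicate 2 by at least 1 bp, which is 61.8% (exact Clopper-Pearson 95% interval 58.8 to 64.8%), against a mean of 0.956% when one list was rotated within its chromosomes (one-sided permutation p = 0.001, the smallest that 1000 rotations can give). The share was 69.6% for the 526 strongest and 46.8% for the 8424 strongest. At the 1044 reproducible peaks with a match in both replicates, the signal of the replicates had a Spearman rho of 0.51 (bootstrap 95% interval 0.46 to 0.56) and a Pearson r of 0.60 on the log2 scale, across peaks, which are not independent replicates. These used the strongest overlapping peak of each replicate, and the peak with the nearest summit gave a rho of 0.460. Over all 17571 relaxed peaks of replicate 1 with a replicate 2 peak, rho was 0.347. All 1053 reproducible peaks were the 1053 strongest of the list called on the pooled replicates. Of them, 840 overlapped the 1053 strongest of replicate 1 and 826 those of replicate 2. Both replicates held 650 of them (61.7%) among their strongest, and neither held 37 (3.51%). Part of this overlap is built in, since the pooled list was derived from both replicates. The rho of 0.51 was likewise taken at peaks selected by their pooled signal, which can itself change a correlation between the replicates.

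**Figure D1:**
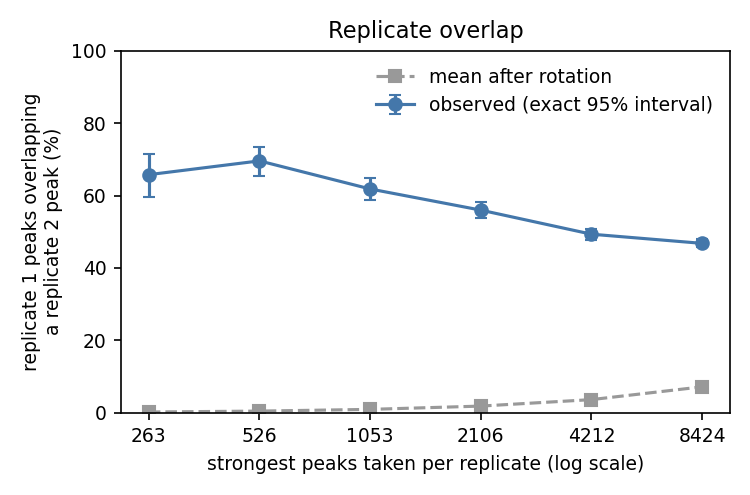
Percent of the strongest peaks of replicate 1 that overlap one of as many strongest peaks of replicate 2 (y axis), against the number of peaks taken from each replicate (x axis, log scale). Circles are observed shares with exact 95% intervals, 61.8% at 1053 peaks, and squares are the mean after rotation within chromosomes, 0.956% there.

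The classes with the largest share of their genes bound, among those tested, were transfer RNA and small nucleolar RNA genes. A summit lay within the promoter window of 218 of 612 tRNA genes, or 35.6% (exact 95% interval 31.8 to 39.6%), against 411 of 19973 protein-coding genes (2.06%). With the strongest peaks of each replicate taken alone, the share of tRNA genes was 34.8% in replicate 1 and 29.1% in replicate 2 (31.9% ± 4.04, SD, n = 2). Of the snoRNA genes, which guide the modification of ribosomal RNA, 74 of 346 were bound (21.4%, interval 17.2 to 26.1%, 20.8% ± 2.04 over the replicates, SD, n = 2). Spliceosomal snRNA genes followed with 9 of 129 (6.98%, interval 3.24 to 12.8%), miRNA genes with 13 of 261 (4.98%, interval 2.68 to 8.37%) and long or other ncRNA genes with 376 of 8058 (4.67%, interval 4.22 to 5.15%). Replicate 1 alone gave higher shares than replicate 2 alone for snRNA genes (12.4% and 6.98%) and miRNA genes (7.28% and 4.98%). Pseudogenes were bound less often than protein-coding genes, at 9 of 2128 (0.423%, interval 0.194 to 0.801%). Rotated peaks gave a mean of 23.2 bound pseudogenes, a difference of -0.666 points, which is smaller than the -1.63 points from protein-coding genes.

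Each of the 6 classes differed from protein-coding genes in Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the classes. The adjusted p was 3.2e-180 for tRNA, 1.8e-48 for snoRNA, 5.5e-30 for long or other ncRNA, 1.5e-09 for pseudogenes, 0.00189 for snRNA and 0.00359 for miRNA genes. RNA genes often lie close together, so 1 peak could count for genes of several classes. With all peaks within 1000 bp of a tRNA or snoRNA gene left out, a setting chosen after the data were seen, long or other ncRNA genes fell to 186 bound (2.31% against 1.65% of protein-coding genes, exact test, adjusted p = 0.000657), and 13 miRNA and 8 snRNA genes were still bound.

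**Figure D2:**
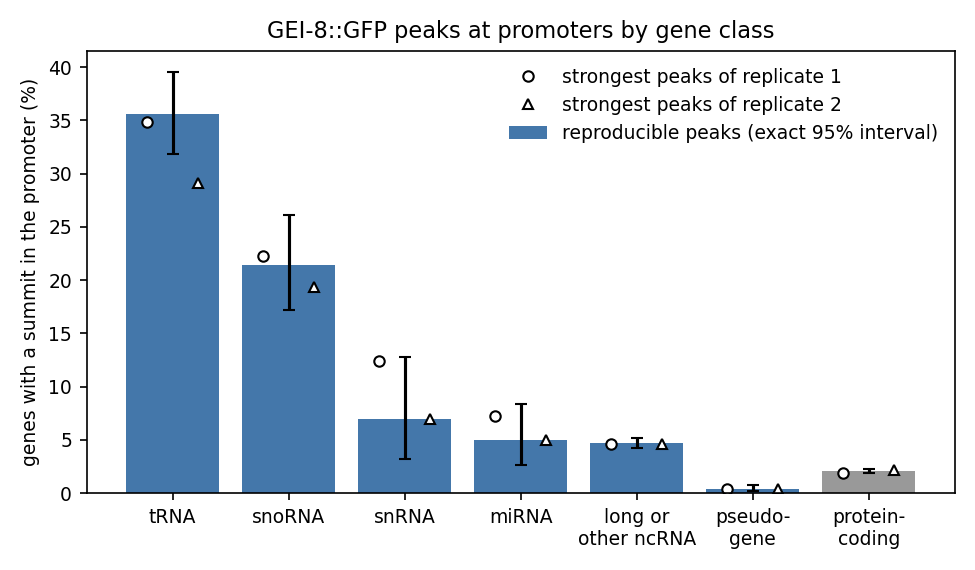
Percent of genes of each class with a summit in the promoter window (y axis), by class. Bars are the reproducible peaks with exact 95% intervals, from 35.6% of tRNA genes to 0.423% of pseudogenes, with protein-coding genes in grey (2.06%), and circles and triangles are the 1053 strongest peaks of replicates 1 and 2.

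Summits sat on the tRNA genes themselves. Within 1000 bp of a tRNA 5′ end there were 199 summits, with a median position 38 bp downstream of it (quartiles 3 and 66 bp), and 190 of them (95.5%) were within 200 bp. Summits near snoRNA genes were centred just upstream, at a median of -31 bp (59 of 87 within 200 bp). Near protein-coding genes the spread was wider, with a median of -185 bp and 139 of 443 summits (31.4%) within 200 bp.

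**Figure D3:**
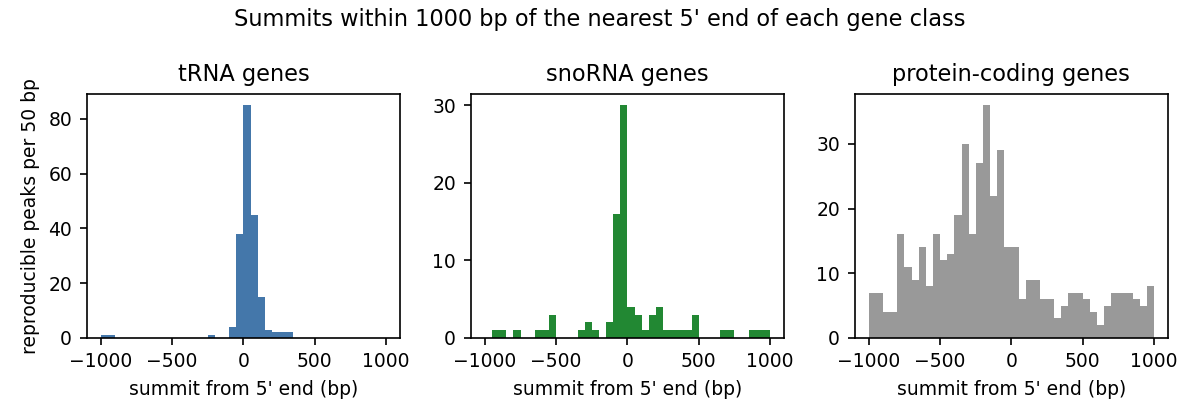
Number of reproducible summits per 50 bp (y axes, each panel on its own scale) by distance in bp from the nearest annotated 5′ end of a tRNA, snoRNA or protein-coding gene (x axes, negative values upstream). The medians are 38, -31 and -185 bp.

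When each reproducible peak was placed in 1 category, 199 (18.9%, exact 95% interval 16.6 to 21.4%) lay within 1000 bp of a tRNA gene, 84 of the rest (7.98%) within 1000 bp of a snoRNA gene, 287 (27.3%) in a protein-coding promoter and 483 (45.9%) elsewhere. Rotation of the peaks within chromosomes gave means of 12.5, 6.95, 217 and 817 peaks (one-sided permutation p = 0.001 for each, the smallest that 1000 rotations can give). Of the 483 peaks elsewhere, 190 were intergenic and 166 were in introns. The 100 strongest peaks held 14 near tRNA genes, 18 near snoRNA genes, 27 in protein-coding promoters and 41 elsewhere.

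Counted on their own, the promoters of protein-coding genes held 361 of the 1053 summits, or 34.3% (33.2% ± 2.55 over the replicates, SD, n = 2). Rotated peaks fell there in 21.0% of cases (central 95% of rotations 18.5 to 23.6%, one-sided permutation p = 0.001, the smallest possible). Promoter peaks and other peaks had similar strength, with median log2 signals of 7.33 and 7.34 and a difference of -0.01 (permutation test with 100000 resamples, two-sided p = 0.684). With the signal of replicate 2 in place of the pooled signal the difference was 0.08 in the other direction and passed the threshold (permutation p = 0.0293), while that of replicate 1 gave -0.02 (p = 0.525).

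Ribosomal protein genes stood out among the protein-coding groups. Peaks lay in the promoters of 13 of 79 (16.5%, exact 95% interval 9.06 to 26.5%), against 2.00% of other genes, and the share was 15.8% ± 2.69 over the replicates (SD, n = 2). Besides rpl-3, the strongest were rps-1 (III, 4475593 to 4475725, summit 258 bp upstream, ranked 69 and 75 in the replicates), which lay inside an annotated RNA gene or pseudogene, and rpl-20 (IV, 4750006 to 4750170, 292 bp upstream, intergenic, ranked 294 and 33). At 4 of the 13 genes the peak was within 1000 bp of a snoRNA gene. Genes of the translation machinery also carried peaks more often than others, 5 of 63 (7.94%, interval 2.63 to 17.6%), with eif-2Bgamma, a subunit gene of a translation initiation factor (II, 6968087 to 6968536, 664 bp upstream, in a coding exon of a neighbouring gene), ears-2, a glutamyl-tRNA synthetase gene (IV, 390273 to 390722, 30 bp upstream, intergenic), and eef-1A.2, a translation elongation factor gene (X, 7823042 to 7823491, 387 bp upstream, intergenic).

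The heterochronic genes, which time larval cell fates, had peaks at 4 of 16 promoters (25%, interval 7.27 to 52.4%). They were nhl-2, a microRNA cofactor gene (III, 4899799 to 4900064, 820 bp upstream, the same peak as at tag-340, ranked 11 and 9), puf-9, a Pumilio-family gene (X, 5841052 to 5841501, 315 bp upstream, inside an annotated RNA gene or pseudogene, ranked 85 and 67), ain-1, a GW182-family gene of microRNA silencing (X, 16612299 to 16612748, 927 bp upstream, intergenic, ranked 105 and 72) and lin-66 (IV, 13887468 to 13887917, ranked 799 and 1146). The list of corepressor, deacetylase and DREAM genes had 5 of 32 (15.6%, interval 5.28 to 32.8%). The strongest was cbp-1, which encodes the p300/CBP acetyltransferase, a coactivator (III, 9765516 to 9765738, 861 bp upstream, intergenic, ranked 15 and 40). The others were weaker, such as lin-53, an RbAp48 histone-binding protein gene (I, 9619756 to 9620205, 221 bp upstream, ranked 1409 and 568), and lin-35, the retinoblastoma gene (I, 5807267 to 5807716, 217 bp upstream, ranked 1451 and 694), both intergenic.

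Of the heat shock genes, 3 of 22 had a peak (13.6%, interval 2.91 to 34.9%), and these were hsp-3, an endoplasmic reticulum chaperone gene (X, 6091996 to 6092445, 97 bp upstream, ranked 98 and 80), hsp-1, the constitutive cytosolic HSP70 gene (IV, 17278489 to 17278662, 368 bp upstream, ranked 144 and 71), and hsp-60, the mitochondrial chaperonin gene (III, 1618913 to 1619362, 604 bp upstream, ranked 156 and 312). The respiratory chain list had 4 of 41 (9.76%, interval 2.72 to 23.1%), among them the cytochrome c oxidase genes cox-6A (III, 5080704 to 5081153, 795 bp upstream), cox-5B (I, 9788492 to 9788941, 8 bp upstream) and cox-5A (III, 12904956 to 12905405, 310 bp upstream). All of the heat shock and cox summits were intergenic.

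Chemoreceptor genes were nearly free of peaks, with 2 of 1310 (0.153%, interval 0.0185 to 0.550%) against 2.19% of other genes. Rotated peaks gave a mean of 12.8 bound members, a difference of -0.825 points, which is smaller than the -2.04 points from other genes. Replicate 1 alone had 4 of 1310 (0.305%) and replicate 2 alone had 3 (0.229%). The 2 were sre-23 (I, 8259472 to 8259675), whose peak was within 1000 bp of a snoRNA gene, and srh-269 (V, 16592122 to 16592571), whose peak was within 1000 bp of a tRNA gene.

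These 28 lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. The adjusted p was 1.1e-07 for ribosomal proteins, 0.00247 for heterochronic genes, 0.00321 for the corepressor list, 0.0398 for the translation, respiratory chain and heat shock lists, and 1.4e-08 for the depletion of chemoreceptors. With a promoter window of 500 bp upstream to 100 bp downstream, ribosomal proteins were the only enriched list. The heat shock call also ended in the exact test with 2 times as many peaks (adjusted p = 0.119), the window of 2000 bp upstream (0.103), any overlap of the whole peak (0.0579) and each peak given to 1 gene (2 of 22, 0.209). In all but the last of these settings the list stayed at 3 of 22. The respiratory chain call also ended in the exact test with the stronger 50% of the peaks (3 of 41, adjusted p = 0.0537) and with 2 times as many (0.148). The corepressor list fell to 1 of 32 with the stronger 50% of the peaks (exact test, adjusted p = 0.584) and to 3 of 32 with each peak given to 1 gene (0.0762). The translation list also lost its call in the exact test with the stronger 50% of the peaks (adjusted p = 0.512), 2 times as many (0.0775), the window of 2000 bp upstream (0.0620) and genes close behind another gene left out (0.192). With replicate 1 alone, the corepressor list (3 of 32, 9.38%, adjusted p = 0.0974) and the translation list (4 of 63, 6.35%, adjusted p = 0.116) did not pass the exact test. With only the peaks that were strong in both replicates, a setting chosen after the data were seen, the corepressor list did not pass either (exact test, adjusted p = 0.634).

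**Figure D4:**
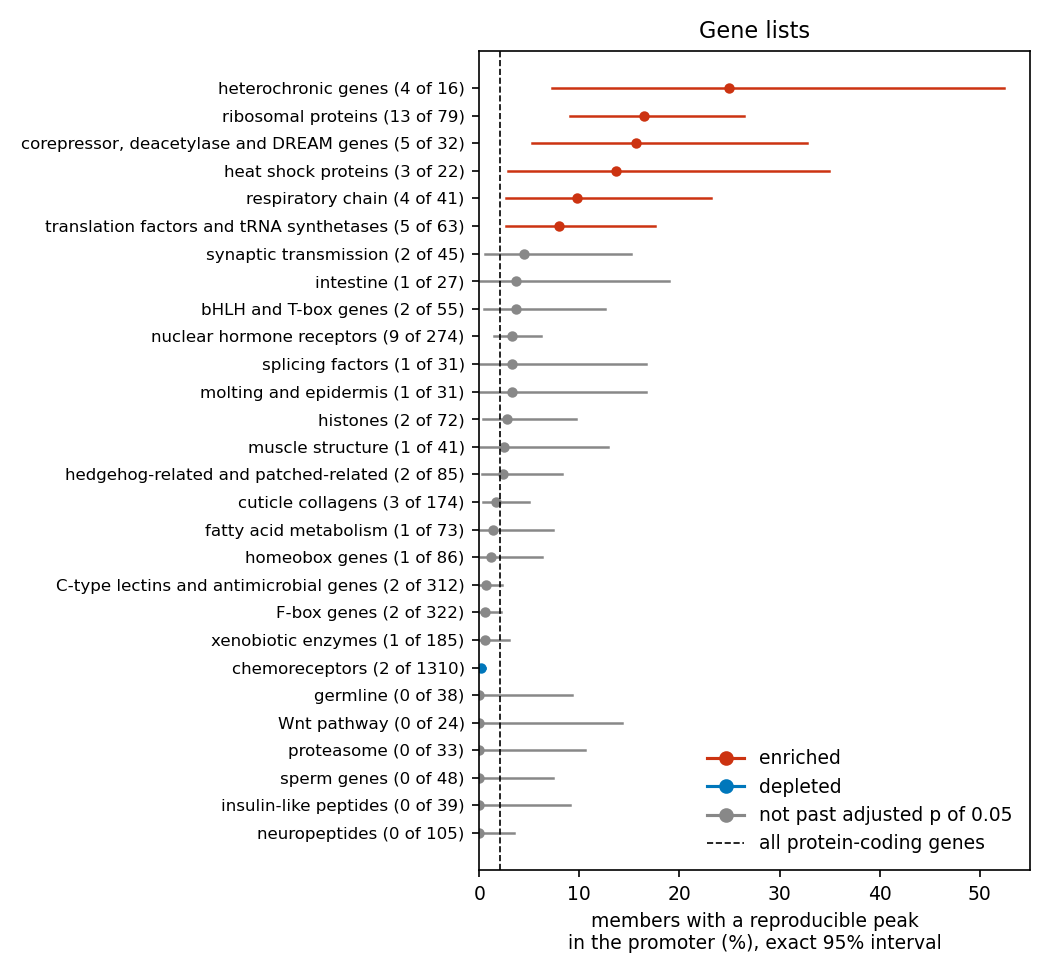
Percent of the members of each of 28 gene lists with a reproducible peak in the promoter (x axis), with exact 95% intervals, and the number of bound and of all members beside each name. Red marks the 6 enriched lists, blue the depleted chemoreceptors (2 of 1310), and the dashed line is the share of all protein-coding genes, 2.06%.

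The other 21 lists did not pass the threshold in the exact test with the reproducible peaks. The highest share among them was that of synaptic transmission with 2 of 45 (4.44%), including egl-30, a Gq alpha subunit gene (I, 1835327 to 1835776, 109 bp upstream). With either replicate alone the share of this list was 2.22%. Intestinal genes had 1 of 27 (3.70%), which was pept-1, a peptide transporter gene (X, 6456522 to 6456971, 125 bp upstream). Their share was also 3.70% in replicate 1 alone, but 11.1% in replicate 2 alone (exact test, adjusted p = 0.0626). The bHLH and T-box genes had 2 of 55 (3.64%), including hlh-11 (III, 9619174 to 9619623, 312 bp upstream). Nuclear hormone receptor genes had 9 of 274 (3.28%, interval 1.51 to 6.14%, exact test, adjusted p = 0.488), and the strongest peak of these was at nhr-68 (V, 11572917 to 11573151, 427 bp upstream, ranked 17 and 18). Against rotated peaks, which gave a mean of 2.76 bound members, this list passed as enriched (permutation test, adjusted p = 0.0420). That test does not compare the list with other genes, and protein-coding promoters in general held more summits than rotation gave. Molting and epidermis genes had 1 of 31 (3.23%), which was myrf-1 (II, 10502569 to 10503018, 253 bp upstream, inside an annotated RNA gene or pseudogene), a transcription factor gene. The other 4 summits named here were intergenic.

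Splicing factors had 1 of 31 (3.23%), histones 2 of 72 (2.78%), muscle structure 1 of 41 (2.44%), hedgehog-related and patched-related genes 2 of 85 (2.35%) and cuticle collagens 3 of 174 (1.72%). Fatty acid metabolism had 1 of 73 (1.37%), homeobox genes 1 of 86 (1.16%), C-type lectins and antimicrobial genes 2 of 312 (0.641%), F-box genes 2 of 322 (0.621%) and xenobiotic enzymes 1 of 185 (0.541%). F-box genes passed as depleted with 2 times as many peaks (exact test, adjusted p = 0.0323), and C-type lectins and antimicrobial genes with peaks near tRNA or snoRNA genes left out (exact test, adjusted p = 0.0394). No member was bound among 105 neuropeptide, 48 sperm, 39 insulin-like peptide, 38 germline, 33 proteasome and 24 Wnt pathway genes, which allows shares of up to 3.45, 7.40, 9.03, 9.25, 10.6 and 14.2% (upper ends of the exact 95% intervals). Histone genes differed between the replicates, with 2.78% bound in replicate 1 and 8.33% in replicate 2, and with replicate 2 alone that list passed the threshold (exact test, adjusted p = 0.0263).

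Peaks were dense on the X chromosome. It held 258 of the 1053 (24.5%, exact 95% interval 21.9 to 27.2%) on 17.7% of the nuclear length, and the share was 23.6% ± 0.537 over the replicates (SD, n = 2). Chromosome III was also above its share of length, with 180 peaks (17.1%, interval 14.9 to 19.5%) on 13.7%, and 22 of these lay within 1000 bp of a tRNA gene. X also carries 276 of the 612 tRNA genes, and 95 of its peaks lay within 1000 bp of one. The promoters of protein-coding genes were bound to a similar extent on X and on the autosomes, 63 of 2731 (2.31%) and 348 of 17242 (2.02%), a difference of 0.289 points that did not pass Fisher's exact test (two-sided p = 0.310). On the autosomes, genes in the central 50% of the chromosome were bound more often, 218 of 9597 (2.27%), than genes in the outer parts, 130 of 7645 (1.70%), with an odds ratio of 1.34 (Fisher's exact test, two-sided p = 0.00880). The stronger 50% of the peaks gave a difference of 0.168 points for this comparison (exact test, p = 0.296), the window of 500 bp upstream 0.323 points (p = 0.0681), and the peaks strong in both replicates, a setting chosen after the data were seen, 0.251 points, against 0.571 points with all peaks, and none of these passed the threshold.

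The summits had sequence features of their own. By the naming rule only enriched 6-mers are named, although some depleted 6-mers had smaller adjusted p. The enriched 6-mers with the smallest adjusted p, named on 1 strand and counted on both, were ACGCAG, found within 50 bp of 142 summits (13.5%, against 1.99% of flanking windows), AGACGC (12.5% against 2.42%), CGTCTC (14.6% against 3.47%), CGAACC (10.5% against 1.95%), AGAGAC (14.9% against 4.23%), GAGAGA (20.9% against 8.02%), CGCAGA (11.4% against 2.47%) and CGAGAG (12.3% against 3.18%). Their adjusted p ran from 1.8e-33 to 1.1e-19 (Fisher's exact test, two-sided, Benjamini-Hochberg over 2080 6-mers). This test treats the summit window and the 2 flanks of a peak as independent sequences and does not use their pairing. All but CGAACC overlap others of the set by several bases when both strands are read, so they need not be separate features. Among the 770 peaks away from tRNA and snoRNA genes, a setting chosen after the data were seen, ACGCAG stood at 14.5% against 1.69% and GAGAGA at 24.8% against 8.51%. CGAACC, which is part of the internal B box promoter of tRNA genes, fell to 3.38% against 1.88% there and was no longer past the threshold (exact test, adjusted p = 0.0825). In all, 573 of the 2080 6-mers were enriched and 338 depleted, and the summit windows had a GC content of 47.3% against 36.3% in the flanks. The flanks were not matched for base composition, and how many of the calls follow from it was not tested.

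The regions around the endogenous copies of gei-8 and unc-119, which the transgene carries, were examined separately, and how much flanking DNA is in the transgene is not given in the sources used here. Around gei-8 (III, 8111168 to 8121232, minus strand) there were 3 reproducible peaks within 20 kb. The strongest (8109472 to 8109921) lay beyond the 3′ end of the gene with its summit 11535 bp downstream of its 5′ end, was ranked 32 in the pooled list, and had a signal of 373. The others were at 8106448 to 8106897 and, 3354 bp upstream of the 5′ end, at 8124361 to 8124810. In the relaxed lists of 30000 peaks per replicate, this window held 37 peaks in replicate 1 and 36 in replicate 2, where 10000 random windows of that width had a median of 15 in each. Fewer peaks were found in 99.8% and 99.6% of those windows. Around unc-119 (III, 10902641 to 10908935, plus strand) there was no reproducible peak, and 6 relaxed peaks in each replicate against medians of 14 and 13.

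**Figure D5:**
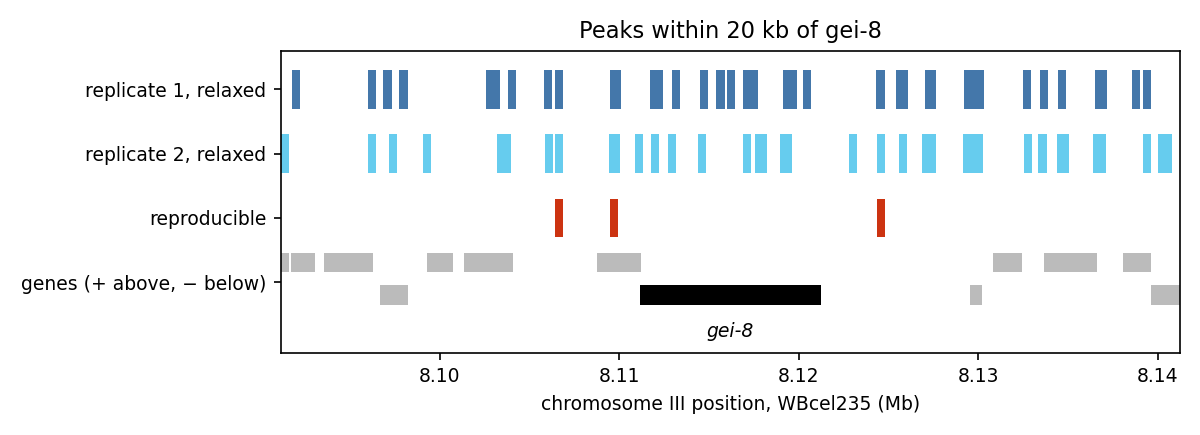
Map of the 20 kb either side of gei-8 on chromosome III (x axis, position in Mb, build WBcel235). Boxes are the relaxed peaks of each replicate (37 and 36), the 3 reproducible peaks, and annotated protein-coding genes above and below the line by strand, with gei-8 in black.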

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

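The settings that kept only peaks strong in both replicates, or left out peaks near tRNA or snoRNA genes, and the rotation test of the RNA classes were chosen after the data were seen. The promoter share stayed above its rotations in all 10 alternatives. The 5 enriched RNA classes and the depleted pseudogenes kept their calls with other windows, numbers of peaks and replicates and in the rotation test. With peaks near tRNA and snoRNA genes left out 3 enriched classes remained, and the difference from protein-coding genes turned to -1.65 points for tRNA genes (-1.82 with only peaks near tRNA genes left out) and -1.65 for snoRNA genes. That reversal follows from the construction, since the peaks at those genes were the ones removed. Ribosomal proteins and chemoreceptors kept their calls in all 13 alternatives, heterochronic genes in 12, the respiratory chain in 10, heat shock proteins and the corepressor list in 8 and the translation list in 7. Leaving out the peaks near gei-8 and unc-119 is 1 of the 13. It left the share of every called list unchanged, so it adds no support to these counts. In place of 6 enriched lists there were 3 with the stronger 50% of the peaks, 3 with 2 times as many peaks, 1 with the window of 500 bp upstream to 100 bp downstream, and 4 to 7 with a replicate left out. The rotation test, which compares each list with moved peaks and not with other genes, also called nuclear hormone receptors (permutation test, adjusted p = 0.0420). The cause of these changes was not tested. The number of reproducible peaks fell to 650 when peaks had to be among the strongest of both replicates. The central against outer difference lost its call with the stronger 50% of the peaks (0.168 points), the window of 500 bp upstream (0.323 points) and the peaks strong in both replicates (0.251 points). Enriched 6-mers numbered 280 with promoter peaks only, which are 361 of 1053, and 499 to 545 with a replicate left out. For gei-8, the mean percent of random windows with fewer relaxed peaks was 99.4 at 10 kb and 96.5 at 40 kb either side, against 99.7 at 20 kb (99.63 to 99.76 with a replicate left out), and for unc-119 it was 14.1 and 15.5 against 9.46 (8.29 to 10.6). The log2 signal difference of promoter peaks was -0.0242 without replicate 2 and turned to 0.0837 without replicate 1 (permutation p = 0.0293), and the cause was not tested. No paired analysis was possible because there was only 1 group. With 2 replicates and unknown depth, differences between lists of few members, such as 4 of 16 genes, rest on single peaks.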

Other observations

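The tests of tRNA copies, amino acid types, ribosomal protein genes as a gauge of transcription, and the density of peaks around gei-8 were chosen after related results were seen, and the tests of single-copy tRNA genes, of each replicate alone and of tRNA genes on X were written before their values were known. Among tRNA genes, those for alanine had the highest share bound, 20 of 34 (58.8%), followed by cysteine with 7 of 13 (53.8%) and aspartate with 13 of 27 (48.1%). Tryptophan was lowest among the standard amino acids with 2 of 12 (16.7%). No amino acid type differed from the other tRNA genes after adjustment over the types (Fisher's exact test, two-sided, smallest adjusted p = 0.115, for alanine). On X 39.1% of tRNA genes were bound and on the autosomes 32.7%, a difference that did not pass the test (108 of 276 against 110 of 336, Fisher's exact test, p = 0.107). Of 343 tRNA genes with no other tRNA gene within 2 kb, 133 were bound (38.8%). The piRNA genes, which are short and lie in clusters, were bound at 57 of 15363 (0.371%), and none of 20 annotated nuclear rRNA genes had a summit in its window. How reads that match several places were treated is not given in the sources used here. The lack of a called peak at rRNA genes therefore need not mean a lack of binding.

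The excess of peaks at tRNA genes can be weighed against technical explanations. Noise of 1 immunoprecipitated library is argued against by the replicates, since the lower of them still had 29.1% of tRNA genes bound. Both replicates were called against the same 1 control alignment, so their agreement cannot speak to noise in that control. Reads shared between copies stay open: only 18 tRNA genes had no other tRNA gene within 10 edits, and 1 of these was bound (5.56%, exact 95% interval 0.141 to 27.3%), a range that includes the 2.06% of protein-coding genes and lies below the 35.6% of all tRNA genes, while genes with a sequence found once were bound at 36 of 143 (25.2%) and those with over 5 exact copies at 157 of 387 (40.6%, Fisher's exact test, two-sided p = 0.00111). Unspecific capture of highly transcribed loci also stays open. Ribosomal protein promoters, which are highly transcribed by another polymerase, were bound at 16.5% against 2.00% of other genes. They were the only list used as a gauge, chosen after related results were seen, and transcription was not measured here. Specific recruitment of GEI-8 would give the same value, and an untagged strain was not analysed here, so the value cannot decide. The reading of the copies and capture values was adjusted after they were seen, and no biological explanation was tested.

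The dense relaxed peaks around gei-8 may come from extra copies of the region in the transgene. Peaks were called against a control alignment, and whether extra copies would raise that control as well was not examined here. The window of 20 kb either side held more relaxed peaks than 99.6% of random windows in the lower replicate (99.63), while in the adjoining 40 kb on either side the counts were 5 and 13 in replicate 1 and 4 and 17 in replicate 2, above 5.90 to 78.8% of random windows. The 3 reproducible peaks there could then partly reflect copy number, and binding of GEI-8 at its own gene cannot be judged from these lists. Around unc-119, the other gene the transgene carries, there were fewer relaxed peaks than in most random windows (6 in each replicate, above 10.6 and 8.29% of windows), which runs against the explanation if its flanks were carried too, but how far the transgene reaches around either gene is not given in the sources used here. No biological explanation was tested.

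The excess of peaks on X is consistent with the tRNA genes it carries. With peaks within 1000 bp of a tRNA gene left out, 163 of 854 were on X, or 19.1% (exact 95% interval 16.5 to 21.9%), a range that includes the 17.7% of nuclear length that X makes up. This was written as a test before the value was seen, but the interval also allows a small excess, and chromosome III, with 22 of its 180 peaks near tRNA genes, was above its share of length as well. No biological explanation was tested.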
